A study of Mus musculus with 9 samples.

How the data were processed

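Messenger RNA was measured in C2C12 cells (CSC12 in the sample titles), a mouse myoblast line that leaves the cell cycle and fuses into myotubes when serum is withdrawn. The 3 genotypes were a knockdown of Fkbp4, a knockdown of Fkbp5 and a control, each collected at days 0, 3 and 5 of differentiation, which gave 9 libraries with 1 library per genotype and day. Per the labels, cells grew in 10% serum, differentiation started at day 0 with 1% insulin-transferrin-selenium, polyA RNA was made into libraries with the TruSeq RNA v2 kit, and sequencing was on a HiSeq2500. The labels also name a second medium after the start of differentiation, and they do not say by which method the genes were knocked down.

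The authors deposited raw read counts per Ensembl gene for each library, without normalisation. Per the labels, the authors used CASAVA 1.8, HISAT2 2.0.2, Subread and featureCounts 1.4.6 with the genome build mm10. The annotation release and the handling of reads that align to several places are not stated. Each of the 9 deposited files of counts listed 47728 genes, of which 47309 were matched by identifier to GENCODE mouse release 21 (GRCm38) for symbols, positions and gene types. The 419 unmatched identifiers held at most 0.0188% of the reads of a library. Reads fell on 23919 genes in at least 1 library.

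Total counts at days 0, 3 and 5 were 4823967, 5568486 and 4719186 in the Fkbp4 knockdown, 3932372, 4356846 and 4863068 in the Fkbp5 knockdown, and 4483183, 4260605 and 4133137 in the control, a range of 1.42-fold. A gene with 0 reads in a library may have reached 3 counts, which is 0.539 to 0.763 CPM (counts scaled to a common library total) depending on the library. Intervals and these floors cover counting error only, since duplicate reads were not separated from independent molecules. Normalised CPM are CPM divided by the normalisation factor, which lay between 0.942 and 1.037.

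With 1 library per genotype and day there are no replicates, and the days of a genotype stood in for them. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3: genes were kept with filterByExpr (12844 genes), libraries were scaled with TMM, and a quasi-likelihood model with genotype and day as additive terms was fitted (4 residual degrees of freedom, biological coefficient of variation 0.126). A knockdown effect is therefore the difference common to the 3 days, and a day effect is the change common to the 3 genotypes. A difference that changes from day to day enlarges the error and can be missed. The change of a knockdown effect between day 0 and the late days 3 and 5 was tested as an interaction with 2 residual degrees of freedom over 13372 genes. All tests were two-sided, p values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Values are log2 fold changes from the edgeR fit over the 9 libraries. Standard errors (SE) were calculated back, as the log2 fold change divided by the square root of its quasi-likelihood F. They are on the log2 scale, also beside a fold value, and add nothing to the fold change and its test.

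Gene lists were tested with camera from limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry. The lists were myogenic transcription factors, myoblast and progenitor state, sarcomere, excitation-contraction coupling and endplate, myoblast fusion, muscle energy metabolism, G1 and S phase regulators, CDK inhibitors, DNA replication, mitosis, FK506-binding proteins and cyclophilins (without Fkbp4 and Fkbp5), Hsp90 chaperone machinery, glucocorticoid receptor targets, p53 targets, interferon response, unfolded protein and integrated stress response, cholesterol synthesis, extracellular matrix, insulin-like growth factor axis, Notch pathway, YAP and TGF-beta targets, immediate early genes, replication-dependent histones, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, and markers of the adipocyte, of the osteoblast and chondrocyte, and of the immune and endothelial lineages. Lists with fewer than 5 tested members received counts only. Single libraries of 1 day were compared without a test, as log2 ratios with exact 95% intervals for the 2 counts, as counts of genes with a 2-fold difference and at least 50 reads in the larger library, and as list medians with their percentile among 10000 random lists of similar expression.

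Groups, models, lists, thresholds, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named Fkbp4, Fkbp5, Cdk4, Myod1, Myog, Myh3, Cdkn1a, Ccnd1, Ccnd3 and Rb1 in any case. In each comparison it further named the 8 called genes with the largest fold change in each direction (5 for day 5 against day 3 and for interactions), with a mean of at least 5 CPM and the same sign in all 3 matched pairs of libraries, without ribosomal protein genes and unnamed models, and 2 to 4 members of each list by smallest p. Other named genes were chosen after their values were seen, and the text says so where they appear.

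After the counts were seen, the 3 prime UTRs of 11387 tested genes were scanned for words of 7 bases whose genes were lower in a knockdown, with UTR length and GC content regressed out and 100 permutations per scan (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; figures with matplotlib 3.10.9). The share of each gene's 31-base words that also occur in another gene was counted from the annotated transcripts. Alternatives were other size factors (RLE), library size alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom, counts thinned to the smallest library, only the 6 libraries compared, a model without the other factor, a minimum 2-fold change, and leaving out each library, day or genotype. A further 3 groups of alternatives were added after the counts were seen, namely protein-coding nuclear genes alone, no genes with a shared 3 prime UTR word, and no genes that share over 20% of their 31-base words.

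The models were tested on simulated data in which 200 genes were changed. Of genes changed 2-fold, 70% to 82% were called in the 6 additive comparisons and 9% and 11% in the interactions. Of genes changed 4-fold, 86% to 95% and 64% and 67% were called. The share of false calls was above the nominal 5% in every comparison, namely 6.4% for the Fkbp5 knockdown against the control, 12.6% for the Fkbp4 knockdown against the control, 11.7% for the knockdowns against each other, 9.2%, 5.2% and 12% for days 3 against 0, 5 against 0 and 5 against 3, and 21.1% and 11.6% for the interactions of the Fkbp5 and the Fkbp4 knockdown. A list of genes lowered by a log2 of −1 was found at −0.979 with an adjusted p of 0.0127 under an estimated correlation. Without a planted effect 0 of 26 lists were called. The genes were simulated independently of each other, so this check cannot show how the list tests behave when genes of a list vary together. Checked on simulated pairs of libraries, 97.2% of the 95% intervals held the true ratio. No library was left out. Reads from the 419 unmatched identifiers stayed in the totals and in the models without a symbol.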

Results

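The series title links the immunophilin Fkbp5 to muscle differentiation through the cell cycle kinase Cdk4. The libraries ask which transcripts change when Fkbp5, or its relative Fkbp4, is depleted in myoblasts before and during differentiation. All values come from 3 libraries per genotype, 1 at each of days 0, 3 and 5.

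Both knockdowns lowered their own target and left the other target's mRNA without a detectable difference. Fkbp5, a peptidyl-prolyl isomerase that acts as an Hsp90 co-chaperone, was 3.29-fold lower in the Fkbp5 knockdown than in the control (log2 fold change −1.72, SE 0.24, adjusted p = 0.00842). Its levels at days 0, 3 and 5 were 4.47, 3.18 and 4.60 CPM in the knockdown and 20.1, 7.34 and 14.8 CPM in the control. These rest on 17, 14 and 21 reads against 91, 31 and 61. Fkbp4, the related co-chaperone FKBP52, was 4.86-fold lower in the Fkbp4 knockdown (−2.28, SE 0.12, adjusted p = 1.97e-05), at 60.1, 27.1 and 24.0 CPM against 240, 143 and 138 CPM. Fkbp4 differed from the control by 0.06 (SE 0.11, adjusted p = 0.857) in the Fkbp5 knockdown, and Fkbp5 by 0.17 (SE 0.19, adjusted p = 0.706) in the Fkbp4 knockdown. On GRCm38, Fkbp5 (ENSMUSG00000024222) lies on chromosome 17 from 28399094 to 28517527 and Fkbp4 (ENSMUSG00000030357) on chromosome 6 from 128429735 to 128438677. The Fkbp5 call passed in 20 of 24 alternative settings. It was missed without the Fkbp5 knockdown day 5 library (−1.77, adjusted p = 0.0536), without day 0 (−1.47, 0.0533), without day 5 (−1.75, 0.0934) and without the day term (−1.78, 1.0).

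**Figure D1:**
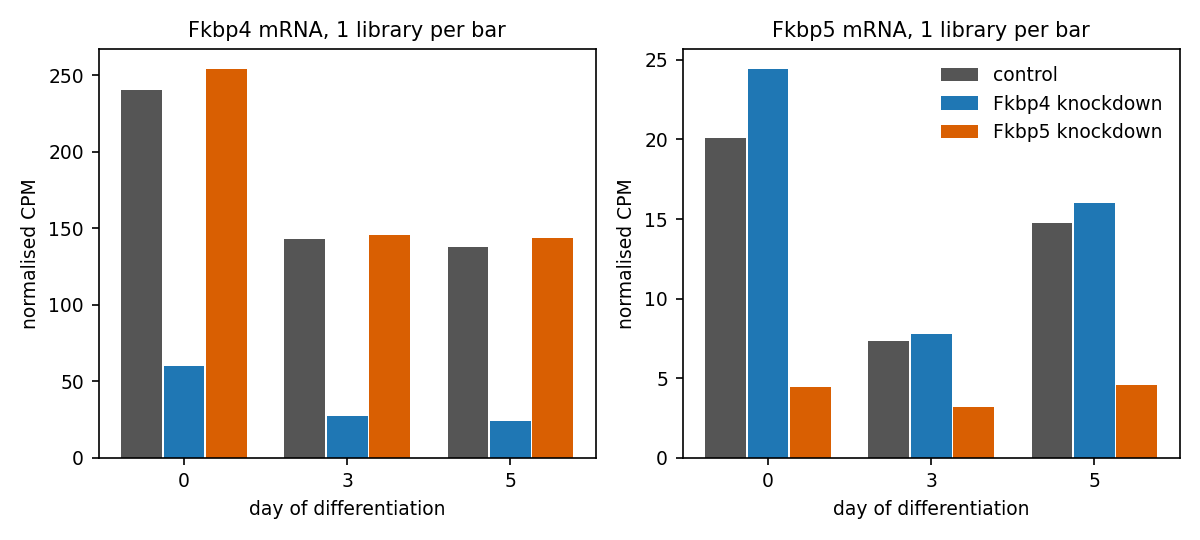
Normalised CPM of Fkbp4 (left) and Fkbp5 (right) at days 0, 3 and 5, 1 library per bar, in the Fkbp4 knockdown, the Fkbp5 knockdown and the control. Fkbp4 lies between 24.0 and 60.1 CPM in its knockdown and between 138 and 240 CPM in the control, and Fkbp5 between 3.18 and 4.60 CPM against 7.34 to 20.1 CPM.

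Of 41 sarcomere genes 10 were lower in the Fkbp5 knockdown than in the control, as in the fast myosin Myh4 and the myosin-binding protein Mybpc1, while the list had adjusted p = 0.35 with an estimated correlation. Myh4 was 10.4-fold lower (−3.38, SE 0.26, adjusted p = 0.00019) and reached 19.9 CPM at day 5 in the knockdown, 234 in the control and 368 in the Fkbp4 knockdown. The slow myosin Myh7 (−1.95, SE 0.29, adjusted p = 0.0108) and the perinatal myosin Myh8 (−1.89, SE 0.30, adjusted p = 0.014) were lower too. These 3 myosins share 30.4%, 38.6% and 32.5% of their 31-base words with other genes, which leaves part of their reads uncertain. Muscle creatine kinase Ckm (−1.10, SE 0.14, adjusted p = 0.00458), the growth factor Igf2 (−0.95, SE 0.11, adjusted p = 0.00347) and the caveolar protein Cav3 (−1.69, SE 0.25, adjusted p = 0.0103) were also lower. Cdk4 mRNA did not pass, with a difference of 0.06 (SE 0.12, adjusted p = 0.861). Its levels at days 0, 3 and 5 were 739, 316 and 300.7 CPM in the knockdown and 660, 378 and 250 CPM in the control, and 31.3% of its words occur in other genes. Myod1 (−0.07), Myog (−0.63, SE 0.25), embryonic myosin Myh3 (−0.67, SE 0.24), the CDK inhibitor Cdkn1a (−0.29, SE 0.12) and Rb1 (−0.34, SE 0.11) did not pass. Neither did the cyclins Ccnd1 (0.42, SE 0.13) and Ccnd3 (0.18), with adjusted p over these genes from 0.137 (Ccnd1) to 0.78 (Myod1). Myh4 (ENSMUSG00000057003) lies on chromosome 11 from 67238029 to 67260446 and Cdk4 (ENSMUSG00000006728) on chromosome 10 from 127063534 to 127067920.

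The largest decreases outside muscle included Rpn2 and Alg10b, 2 genes of N-glycosylation, a process for which no list was tested. Both hold the 3 prime UTR word GTTCGTT, which led the scan of the Fkbp5 knockdown described below. The oligosaccharyltransferase subunit Rpn2 (−1.73, SE 0.10, adjusted p = 3.57e-05) stood at 62.9 to 84.6 CPM against 226 to 248 CPM in the control, and the glucosyltransferase Alg10b was 3.11-fold lower (SE 0.11, adjusted p = 0.000103). The secreted Wnt modulator Dkk3 (−2.11, SE 0.35, adjusted p = 0.0161) and the guanylate-binding proteins Gbp8 (−1.86, SE 0.26) and Gbp9 (−1.71, SE 0.32) were lower as well. Gbp8 shares 31.2% of its 31-base words with other genes. The largest increases were in mt-Nd3 (6.99, SE 1.42, adjusted p = 0.0352) and mt-Nd4l (6.47, SE 1.16, adjusted p = 0.0235), subunits of respiratory complex I. Their reads came from the Fkbp5 knockdown day 5 library, with 595 and 992 CPM there and at most 4.11 CPM elsewhere. The collagen Col27a1 (2.84-fold, SE 0.25), the mitochondrial adaptor Mgarp (1.46, SE 0.26) and the peptide transporter Tap2 (1.30, SE 0.17, adjusted p = 0.00604) followed. Next came the adaptor Nyap1 (1.25, SE 0.26), the leukotriene pathway protein Alox5ap (1.24, SE 0.19) and the syndecan Sdc3 (1.19, SE 0.17).

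Across the muscle lists, 10 of 41 sarcomere genes were lower and 0 higher (28 lower adjusted over the list alone). These were Myh4, Mybpc1 (−1.69, SE 0.22), Myh7, the actinin Actn3 (−0.77, SE 0.12), Myh8, the myosin chaperone Unc45b (−1.03), Lmod3 (−0.67), Myoz2 (−1.08), cardiac actin Actc1 (−1.03) and Tnnt3 (−0.84). The sarcomere median was −0.54 (camera adjusted p = 5.95e-11, adjusted p = 0.35 with an estimated correlation and 0.117 with fry). At day 0 it was −0.01, with 20 genes higher and 21 lower. Sarcomere genes such as Mybpc1 had hardly any reads at day 0, and the prior count draws the ratios of such genes towards no difference. Of 24 genes for excitation-contraction coupling and the endplate, 5 were lower (13 adjusted over the list alone), among them the acetylcholine receptor subunits Chrnd (−0.85, SE 0.12) and Chrng (−0.62, SE 0.12) and the junctional protein Jph1 (−0.67, SE 0.12). Their median was −0.35 (adjusted p = 1.1e-05, adjusted p = 0.35 with an estimated correlation). At day 0 alone the coupling and endplate median was −0.31, with 8 genes higher and 16 lower. Of 15 myogenic transcription factors, Tead4 (−0.75, SE 0.12), Rbm24 (−0.93), Eya4 (−0.65) and Mef2d (−0.40) were lower (7 adjusted over the list alone). This list had a median of −0.42 (adjusted p = 0.000185, adjusted p = 0.35 with an estimated correlation). At day 0 alone the myogenic factor median was −0.15, with 5 genes higher and 10 lower. Cav3 was the 1 gene lower of 21 for myoblast fusion (list adjusted p = 0.716; 1 higher and 1 lower adjusted over the list alone). Ckm was the 1 lower of 18 for muscle energy metabolism (list 0.172; 3 lower adjusted over the list alone). Of 18 genes of the progenitor state, Cd34 was higher (1.03, SE 0.14, adjusted p = 0.00749; list 0.716; 2 adjusted over the list alone).

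In the cell cycle lists, Cdk6, a paralogue of Cdk4 that binds the same D-type cyclins, was lower (−0.99, SE 0.14), as was E2f2 (−0.90, SE 0.13), both at an adjusted p of 0.00849. They were the only 2 of 27 G1 and S phase regulators called (2 adjusted over the list alone; list adjusted p = 0.619). None of 5 CDK inhibitors was called (list 0.716), with Cdkn1c at −1.54 (adjusted p = 0.113) as the 1 lower adjusted over the list alone. Of 48 DNA replication genes and 53 mitosis genes 0 were called by edgeR or adjusted over the list alone, with medians of −0.08 (adjusted p = 0.177) and 0.08 (adjusted p = 0.395). The mitosis median was −0.24 (adjusted p = 0.00247) without the Fkbp5 knockdown day 3 library and 0.32 without its day 5 library.

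The collagens Col1a1 (0.85, SE 0.16), Col4a2 (0.72, SE 0.15) and Col18a1 (0.53, SE 0.12) were higher and were the 3 of 42 matrix genes called (12 higher and 2 lower adjusted over the list alone). Outside the list, and picked after its value was seen, Col23a1 was lower (−2.20, SE 0.45, adjusted p = 0.0352). The matrix median was 0.23 (adjusted p = 9.81e-05, adjusted p = 0.376 with an estimated correlation). Interferon response genes were higher as a list (median 0.32, adjusted p = 5.57e-05, adjusted p = 0.35 with an estimated correlation). None of its 23 genes was called, 1 adjusted over the list alone, with Bst2 at 0.95 (adjusted p = 0.0695) and Tap1 at 1.41 (0.12). Immediate early genes were lower as a list (median −0.33, adjusted p = 2.83e-05, adjusted p = 0.35 with an estimated correlation). Here 0 of 25 were called and 2 were lower adjusted over the list alone, with Zfp36 at −0.76 (adjusted p = 0.0692) and Egr1 at −0.79 (0.159). Of 13 mitochondrially encoded genes 4 were higher (6 adjusted over the list alone), including mt-Nd2 (0.64, SE 0.12) and mt-Cytb (0.59, SE 0.11). The other 2 called, mt-Nd3 and mt-Nd4l, were high in the Fkbp5 knockdown day 5 library alone. The list median was 0.64 (adjusted p = 5.89e-05, adjusted p = 0.376 with an estimated correlation), and 0.30 for the 5 members outside a stretch copied on chromosome 1, left out after the counts were seen (adjusted p = 0.00675 at the preset correlation).

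Small shifts without a called gene were found for 84 ribosomal protein genes (median 0.10, adjusted p = 0.00136) and 25 cholesterol synthesis genes (−0.13, adjusted p = 0.0147). Both had an adjusted p = 0.908 with an estimated correlation. The ribosomal call was lost without the Fkbp5 knockdown day 0 library (0.816) or the control day 5 library (0.105). The cholesterol call was lost without the Fkbp5 knockdown day 3 (0.0592) or day 5 library (0.435) or the control day 0 (0.0955) or day 5 library (0.648).

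The remaining lists did not pass in the Fkbp5 knockdown. Igf2 was the 1 gene lower of 18 in the insulin-like growth factor axis (list adjusted p = 0.118; 1 higher and 2 lower adjusted over the list alone). The kinase inhibitor Errfi1 was the 1 lower of 21 glucocorticoid receptor targets (−0.77, SE 0.12, adjusted p = 0.0131; list 0.408; 1 adjusted over the list alone). The complex I subunit Ndufc2 was the 1 lower of 78 nuclear-encoded oxidative phosphorylation genes (−0.64, SE 0.11; list 0.716; 1 adjusted over the list alone). No gene was called by edgeR or adjusted over the list alone among FK506-binding proteins and cyclophilins, a list fixed without Fkbp4 and Fkbp5 (0 of 27, list 0.716), the Hsp90 chaperone machinery (0 of 34, 0.394), p53 targets (0 of 24, 0.8) and the unfolded protein and integrated stress response (0 of 30, 0.581). The same held for the Notch pathway (0 of 14, 0.716), YAP and TGF-beta targets (0 of 20, 0.716) and replication-dependent histones (0 of 9, 0.716). Of the markers of other lineages, 0 of 4 adipocyte, 0 of 4 osteoblast and chondrocyte and 0 of 2 immune and endothelial genes were called. Adjusted over the list alone, 1 adipocyte marker was higher and 1 lower, and 1 osteoblast or chondrocyte marker was higher.

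In total, 268 of 12844 genes differed between the Fkbp5 knockdown and the control, 88 higher and 180 lower, of which 94 changed at least 2-fold. DESeq2 called 241 and limma voom 323. The count was 40 without the Fkbp5 knockdown day 5 library, 113, 51 and 54 without the control library of day 0, 3 or 5, and 128, 41 and 36 without day 0, 3 or 5 altogether. It was 866 with no low-count filter. With gene sets chosen after the counts were seen, it was 413 for protein-coding nuclear genes and 446 without genes that share over 20% of their words. It was 41 without genes whose 3 prime UTR holds a leading 7-base word of either knockdown or 6 bases of it. That last setting tested 7719 genes, 1058 of them at an unadjusted p under 0.05 (edgeR), against 2027 of 12844 in the main fit. The fall in the count is therefore not a measure of what the word of the Fkbp5 knockdown accounts for. Of 39 called genes among those named or listed, Rpn2 and Alg10b passed in every setting that tested them. Both hold a leading word, so the setting without word holders left them out. Myh4 was missed without the Fkbp5 knockdown day 5 library (−2.21, adjusted p = 0.0602), without day 5 (−2.29, 0.226) and without the day term (−3.44, 1.0). Without the Fkbp5 knockdown day 5 or the control day 5 library, Mybpc1 (adjusted p = 0.28 and 0.233) and Ckm (0.0532 and 0.0539) were missed, and Cdk6 (0.056) without the former. The Fkbp5 knockdown day 5 library stood apart, with 10.06% mitochondrial reads against 4.01% and 5.01% in the control and Fkbp4 knockdown of day 5. Its chi-square per degree of freedom was 27.8 against its control, where the other 5 same-day pairs with a control lay between 9.36 and 11.5. That value includes mitochondrial genes such as mt-Co2 (10921 against 33.6 CPM) and mt-Co3 (10440 against 34.8 CPM). It was not computed without them, so it does not show a difference across all genes.

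**Figure D2:**
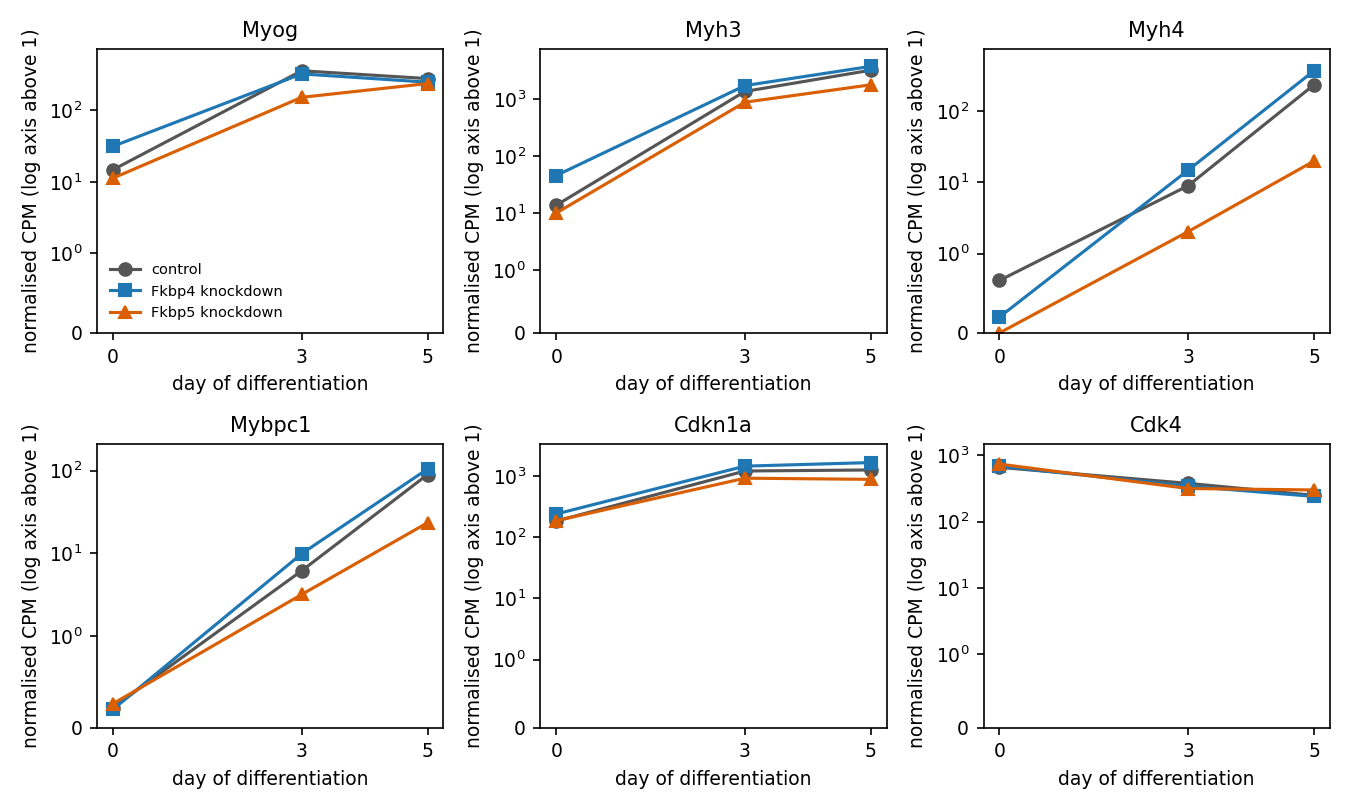
Normalised CPM of Myog, Myh3, Myh4, Mybpc1, Cdkn1a and Cdk4 at days 0, 3 and 5 on an axis that is logarithmic above 1, 1 library per point, in the Fkbp4 knockdown, the Fkbp5 knockdown and the control. At day 5 Myh4 reached 19.9 CPM in the Fkbp5 knockdown, 234 in the control and 368 in the Fkbp4 knockdown.

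In the Fkbp4 knockdown, used in the series beside Fkbp5, 106 of the 140 genes called against the control were lower. After Fkbp4 itself the largest decreases were in the hydroxysteroid dehydrogenase Akr1c14 (−1.85, SE 0.25) and the extracellular superoxide dismutase Sod3 (−1.73, SE 0.23), both at an adjusted p of 0.0112. The protease inhibitor Ctla2a (−1.42, SE 0.28), the alcohol dehydrogenase Adh1 (−1.37, SE 0.26) and the mitochondrial transfer RNA mt-Tc (−1.36, SE 0.21) followed. The matrix protein asporin Aspn (−1.34, SE 0.21) and the growth factor Igf1 (−1.27, SE 0.19, adjusted p = 0.0173) were lower too. Higher were the chemokine Cxcl13 (1.85, SE 0.29, adjusted p = 0.0194), the ligand Wnt7b (1.67, SE 0.30, adjusted p = 0.0306), the autophagy gene Atg9b (1.47, SE 0.24) and the protease Tmprss11b (1.30, SE 0.20). The phosphatase Ppef1 (1.16, SE 0.18) and the pentraxin Nptx1 (0.98, SE 0.11, adjusted p = 0.00684) were higher too. Cdk4 differed by −0.05 (SE 0.12, adjusted p = 0.868), Myod1 by 0.00 (0.993), Myog by 0.14 (0.818) and Myh3 by 0.68 (SE 0.24, 0.203), and none of these passed. Cdkn1a (0.35, adjusted p = 0.21), Ccnd1 (0.58, SE 0.13, 0.0616), Ccnd3 (−0.04, 0.851) and Rb1 (0.16, 0.493) did not pass either.

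Of 84 ribosomal protein genes 2 were lower in the Fkbp4 knockdown (7 adjusted over the list alone), Rpl22l1 (−0.75, SE 0.09, adjusted p = 0.00684) and Rps15a (−0.55, SE 0.11). The ribosomal median was −0.23 (adjusted p = 2.9e-10, adjusted p = 0.773 with an estimated correlation). Of 78 nuclear-encoded oxidative phosphorylation genes 2 were lower (13 adjusted over the list alone), the complex I subunit Ndufa1 (−1.19, SE 0.16) and the ATP synthase subunit Atp5l (−0.72, SE 0.13). Their median was −0.19 (adjusted p = 1.49e-08, adjusted p = 0.773 with an estimated correlation). Periostin Postn (−1.07, SE 0.21) was the 1 of 42 matrix genes called (2 higher and 10 lower adjusted over the list alone). The matrix median was −0.26 (adjusted p = 0.00112, adjusted p = 0.773 with an estimated correlation). Among 27 FK506-binding proteins and cyclophilins other than Fkbp4 and Fkbp5, Ppic was lower (−0.65, SE 0.12; 5 adjusted over the list alone). That list had a median of −0.14 (adjusted p = 0.00264, adjusted p = 0.773 with an estimated correlation).

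Of the muscle lists, coupling and sarcomere genes were higher as lists in the Fkbp4 knockdown and the others did not pass. Chrnd (0.59, SE 0.12, adjusted p = 0.0479) was the 1 of 24 coupling and endplate genes called (5 adjusted over the list alone). Their median was 0.28 (adjusted p = 0.00153, adjusted p = 0.773 with an estimated correlation). None of 41 sarcomere genes was called, 1 higher adjusted over the list alone. The sarcomere median was 0.31 (adjusted p = 0.000442, adjusted p = 0.773 with an estimated correlation), and 0.11 (adjusted p = 0.272) without the control day 0 library.

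Several genes of the other lists passed in the Fkbp4 knockdown while their lists did not. N-cadherin Cdh2 was higher (0.49, SE 0.09) and the tetraspanin Cd9 lower (−0.56, SE 0.10) among 21 fusion genes (list adjusted p = 0.511; 4 higher and 2 lower adjusted over the list alone). E2f2 was higher (0.63, SE 0.12) and Tfdp2 lower (−0.64, SE 0.12) among G1 and S phase regulators (list 0.501). The co-chaperones Bag3 (−0.63, SE 0.10) and Ttc9 (−0.57, SE 0.10) were lower among Hsp90 chaperone genes (list 0.173). Igf1 and Igfbp7 (−1.05, SE 0.19) were lower in the insulin-like growth factor axis (list 0.97), where the test pointed down and the median, 0.06, up. Ifi27 (−0.66, SE 0.11) was lower among interferon response genes (list 0.489) and the lipoprotein lipase Lpl (−1.08, SE 0.19) among 4 adipocyte markers. Fosl1 was higher (0.74, SE 0.14) among immediate early genes (list 0.544). No gene was called among myogenic transcription factors (list 0.126; 2 higher adjusted over the list alone), the progenitor state (0.532), energy metabolism (0.203), CDK inhibitors (0.501), DNA replication (0.173) and mitosis (0.113). The same held for glucocorticoid receptor targets (0.266), p53 targets (0.332), the unfolded protein response (0.203), cholesterol synthesis (0.833), Notch (0.552), YAP and TGF-beta targets (0.126) and histones (0.97). Mitochondrially encoded genes did not pass (0.2), with a median of −0.27 and a mean of 0.28. Without the stretch copied on chromosome 1, left out after the counts were seen, their list was lower at the preset correlation (5 members, median −0.30, adjusted p = 0.00303), and an estimated correlation was not tried.

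In total, 140 of 12844 genes differed between the Fkbp4 knockdown and the control, 34 higher and 106 lower, 41 of them at least 2-fold. DESeq2 called 224 and limma voom 187. The count was 8 and 14 without the Fkbp4 knockdown library of day 3 or 5, 40, 4 and 20 without the control library of day 0, 3 or 5, and 86, 4 and 12 without day 0, 3 or 5 altogether. It was 224 and 259 without the Fkbp5 knockdown library of day 0 or 3, and 690 with no low-count filter. With the same gene sets chosen after the counts were seen, it was 240, 312 and 20, the last over 7719 genes. Of 33 called genes among those named or listed, none passed in every setting, and Fkbp4 itself was missed only without the day term (−2.23, adjusted p = 0.881). Igf1 was missed without the Fkbp4 knockdown day 3 (adjusted p = 0.137) or day 5 library (0.0693) and without the control day 3 (0.15) or day 5 library (0.0966).

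Set against each other, the knockdowns differed more than either did from the control, and 23 of 41 sarcomere genes were lower in the Fkbp5 knockdown. Myh4 was 16.0-fold lower in the Fkbp5 than in the Fkbp4 knockdown (log2 SE 0.25, adjusted p = 2.97e-05), and Myh7 (−2.45, SE 0.28) and Myh8 (−2.11, SE 0.30) were lower. Myh3 (−1.36, SE 0.24, adjusted p = 0.00706), Cdkn1a (−0.64, SE 0.12, adjusted p = 0.0097) and Rb1 (−0.50, SE 0.11, adjusted p = 0.0146) were lower as well, the Cdkn1a call being lost without the Fkbp4 knockdown day 5 (0.0651) or the Fkbp5 knockdown day 5 library (0.0619). Myog (−0.78, SE 0.26, adjusted p = 0.0712), Cdk4 (0.11, SE 0.12, 0.575), Myod1 (−0.07, 0.674), Ccnd1 (−0.17, 0.409) and Ccnd3 (0.22, 0.131) did not pass. Further decreases were in the unconventional myosin Myo7b (−3.70, SE 0.49), Wnt7b (−3.05, SE 0.35), the glycosyltransferase Galnt6 (−2.80, SE 0.31), the CDK inhibitor Cdkn1c (−2.64, SE 0.41) and the adhesion molecule Nrcam (−2.17, SE 0.36). The largest increases were in mt-Nd4l (7.27, SE 1.21) and mt-Nd3 (6.48, SE 1.35), which rest on the Fkbp5 knockdown day 5 library, and in the nucleosome-binding protein Hmgn2 (3.13, SE 0.61). Fkbp4 (2.34, SE 0.12), Apol6 (2.09, SE 0.30), Akr1c14 (1.95, SE 0.25), Eif5a2 (3.49-fold, SE 0.26) and Ctrb1 (1.77, SE 0.28) followed. Fkbp5 was lower (−1.89, SE 0.23, adjusted p = 0.00116).

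Of 41 sarcomere genes 23 were lower in the Fkbp5 than in the Fkbp4 knockdown and 0 higher (36 lower adjusted over the list alone), among them Actn3 (−1.18, SE 0.12) and Actc1 (−1.88, SE 0.21). The sarcomere median was −0.81 (adjusted p = 1.85e-13, adjusted p = 0.277 with an estimated correlation). Of 24 coupling and endplate genes 13 were lower (15 adjusted over the list alone), led by Chrnd (−1.44, SE 0.12) and Chrng (−1.13, SE 0.12). Their median was −0.58 (adjusted p = 3.44e-07, adjusted p = 0.277 with an estimated correlation). Of 15 myogenic factors 8 were lower (11 adjusted over the list alone), led by Rbm38 (−0.82, SE 0.14) and Mef2d (−0.52, SE 0.09). This list had a median of −0.54 (adjusted p = 1.73e-05, adjusted p = 0.277 with an estimated correlation). Of 25 immediate early genes 8 were lower (8 adjusted over the list alone), as in Dusp5 (−0.99, SE 0.17). Here the median was −0.33 (adjusted p = 9.93e-05, adjusted p = 0.277 with an estimated correlation).

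Of 42 matrix genes 18 were higher in the Fkbp5 than in the Fkbp4 knockdown and 2 lower (27 and 2 adjusted over the list alone), as in Col1a1 (1.28, SE 0.17), Postn (1.49, SE 0.20) and Col8a1 (1.44, SE 0.21). The matrix median was 0.45 (adjusted p = 1.09e-07, adjusted p = 0.277 with an estimated correlation). Of 84 ribosomal protein genes 26 were higher (46 adjusted over the list alone), as in Rpl22l1 (0.83, SE 0.09). The ribosomal median was 0.34 (adjusted p = 9.68e-13, adjusted p = 0.427 with an estimated correlation). Interferon response genes were higher as a list (5 of 23, median 0.55, adjusted p = 0.00025, adjusted p = 0.277 with an estimated correlation). So were FK506-binding proteins and cyclophilins other than the targets (7 of 27, median 0.16, adjusted p = 0.00944, adjusted p = 0.277 with an estimated correlation). Oxidative phosphorylation genes were higher as a list (12 of 78 and 1 lower, median 0.20, adjusted p = 6.23e-05, adjusted p = 0.748 with an estimated correlation). Mitochondrially encoded genes were too (8 of 13, median 0.94, adjusted p = 8.8e-05, adjusted p = 0.409 with an estimated correlation). Their median was 0.56 for the 5 members outside the copied stretch (adjusted p = 0.000119 at the preset correlation).

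Among single genes of the other lists, Cd34 (1.72, SE 0.14, adjusted p = 0.000179), Cd9 (0.97, SE 0.10) and Lpl (1.67, SE 0.19) were higher in the Fkbp5 than in the Fkbp4 knockdown. E2f2 (−1.53, SE 0.12), Cdk6 (−1.26, SE 0.13), Igf2 (−1.09, SE 0.11) and Ckm (−1.34, SE 0.13) were lower, while myoglobin Mb (1.60, SE 0.29) went against its list. The energy metabolism (median −0.29, adjusted p = 0.0278), DNA replication (−0.14, 0.0268) and cholesterol (−0.18, 0.0427) lists were lower. They had adjusted p of 0.427, 0.761 and 0.792 with an estimated correlation. The energy metabolism call was lost without Fkbp4 knockdown day 0 (0.0711) or Fkbp5 knockdown day 5 (0.104). The DNA replication call was lost without Fkbp4 knockdown day 0 (0.0547) or day 5 (0.499) or Fkbp5 knockdown day 5 (0.0954). That of cholesterol was lost without Fkbp4 knockdown day 3 (0.705) or Fkbp5 knockdown day 3 (0.146) or day 5 (0.327). In total 1650 of 12844 genes differed, 877 higher and 773 lower in the Fkbp5 knockdown (DESeq2 1094, limma voom 1828). Which direction was larger depended on the scaling, as library size alone gave 1637, 620 higher and 1017 lower. The count was 968, 790 and 539 without the Fkbp4 knockdown library of day 0, 3 or 5, 487 without the Fkbp5 knockdown day 5 library, and 806 and 250 without day 0 or day 5. It was 718 of 7719 genes without those holding a leading word or 6 bases of it, a set chosen after the counts were seen.

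Differentiation itself, the change common to the 3 genotypes, raised sarcomere genes and lowered DNA replication and mitosis genes between days 0 and 3. Myog, the transcription factor that starts terminal differentiation, rose 14.2-fold (3.83, SE 0.28, adjusted p = 1.74e-06), Myh3 64.3-fold (6.01, SE 0.29) and Cdkn1a 5.79-fold (2.53, SE 0.13). Ccnd3 rose 5.00-fold (SE 0.09), Rb1 3.72-fold (SE 0.11) and Myod1 1.66-fold (SE 0.09). Cdk4 fell 2.01-fold (SE 0.12, adjusted p = 4.73e-05), Ccnd1 3.34-fold (−1.74, SE 0.13), Fkbp4 1.85-fold (−0.89, SE 0.11) and Fkbp5 2.55-fold (−1.35, SE 0.22, adjusted p = 0.000433). The natriuretic peptide Nppc had 0 reads in all 3 day 0 libraries and 7.60 to 12.3 CPM at day 3. The scavenger receptor Scara5, the matrix protein Cilp, Cav3, Adh1 and the transporter Slc6a2 stood at up to 0.263 CPM at day 0. At day 3 they reached 19.3 to 41.6, 5.48 to 22.3, 3.41 to 16.8, 4.95 to 14.2 and 12.6 to 27.0 CPM. Myh7b (6.29, SE 0.36) and the actin nucleator Lmod2 (6.29, SE 0.37) rose 78.4-fold each. Among genes that fell, the placental lactogen relatives Prl2c2 (−7.54, SE 0.42) and Prl2c3 (−6.73, SE 0.35) share 93% and 86% of their words with other genes. The carbonic anhydrase relative Car8 (−5.99, SE 0.37), Serpinb2 (−5.90, SE 0.43), Itgb7 (−5.84, SE 0.25), Cxcl5 (−5.36, SE 0.31) and Ngfr (−5.27, SE 0.32) fell, and the interleukin antagonist Il1rn went from 15.8 to 28.3 CPM to at most 0.177 CPM.

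At day 3 against day 0, 40 of 41 sarcomere genes were higher (40 adjusted over the list alone), led by Lmod3 (4.94, SE 0.17) and Tnni2 (5.27, SE 0.19). The sarcomere median was 4.46 (adjusted p = 2.01e-20, adjusted p = 0.246 with an estimated correlation). Of 24 coupling and endplate genes 23 were higher, as in Chrng (4.64, SE 0.13), at a list median of 2.88 (adjusted p = 5.37e-14, adjusted p = 0.246 with an estimated correlation). Of 15 myogenic factors 13 were higher and 1 lower, at a list median of 1.53 (adjusted p = 1.43e-05, adjusted p = 0.246 with an estimated correlation). Of 48 DNA replication genes 46 were lower (47 adjusted over the list alone), as in Mcm5 (−2.07, SE 0.10), with adjusted p = 5.57e-20 for the list and adjusted p = 0.246 with an estimated correlation. All 53 mitosis genes were lower, as in Mybl2 (−3.15, SE 0.21), with adjusted p = 3.67e-15 for the list and adjusted p = 0.413 with an estimated correlation. Of 84 ribosomal protein genes 73 were lower, at a median of −0.70 (adjusted p = 3.67e-14, adjusted p = 0.352 with an estimated correlation).

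Other lists were higher at day 3. Among 21 fusion genes 11 were higher and 3 lower, as in Mymk (5.05, SE 0.21), with adjusted p = 0.00522 and adjusted p = 0.3 with an estimated correlation. Among 18 energy genes 13 were higher and 2 lower, as in Ckm (5.45, SE 0.18), with adjusted p = 0.0021 and adjusted p = 0.297 with an estimated correlation. Cholesterol synthesis (21 of 25, as in Fdft1 at 3.49-fold, SE 0.12) had adjusted p = 4.32e-06 and adjusted p = 0.413 with an estimated correlation. Matrix (26 higher and 8 lower of 42, as in Dcn at 4.73, SE 0.21) had adjusted p = 0.00811 and adjusted p = 0.413 with an estimated correlation. Notch (9 higher and 3 lower of 14, as in Dll1 at 3.42, SE 0.20) had adjusted p = 0.0119, and histones (6 of 9) 0.00255, both with adjusted p = 0.246 with an estimated correlation. Mitochondrially encoded genes (7 of 13) had adjusted p = 0.0235 and adjusted p = 0.481 with an estimated correlation, and this call was lost without the Fkbp5 knockdown day 0 (0.0581) or the control day 3 library (0.0709). In lists that did not pass, the progenitor genes Hmga2 (−4.35, SE 0.19) and Id3 (−2.92, SE 0.16), Ccne2 (−2.48, SE 0.14), Fosl1 (−3.01, SE 0.13) and osteopontin Spp1 (−4.52, SE 0.15) fell. Igf2 (5.91, SE 0.16), H19 (4.14, SE 0.16), E2f2 (1.57, SE 0.12), Cdkn1c (5.68, SE 0.48) and the p53 target Eda2r (2.40, SE 0.10) rose.

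By day 5, Myh4 had risen 660-fold over day 0 (9.37, SE 0.32, adjusted p = 1.3e-08), Actn2 251-fold (7.97, SE 0.40), Myh3 141-fold (7.14, SE 0.30) and Myog 13.9-fold (SE 0.28). Cilp, Cav3, Mybpc1 and Adamts16, at up to 0.263 CPM at day 0, reached 24.2 to 82.4, 16.0 to 43.1, 23.4 to 105 and 18.8 to 24.7 CPM, and Nppc 9.86 to 12.6 CPM. The cytochrome oxidase subunit mt-Co2 (7.69, SE 1.45, adjusted p = 0.000983) rose through 2 of the 3 day 5 libraries. Cdk4 was 2.64-fold lower at day 5 than at day 0 (−1.40, SE 0.12, adjusted p = 3.7e-06), Ccnd1 4.51-fold (SE 0.13) and Fkbp4 1.94-fold (SE 0.11). Fkbp5 did not pass (−0.43, SE 0.20, adjusted p = 0.094). Itgb7 (−7.64, SE 0.31), Car8 (−6.89, SE 0.42), Igsf5 (−5.77, SE 0.38) and the hedgehog inhibitor Hhip (−5.24, SE 0.27) were among the largest decreases. At day 5, 41 of 41 sarcomere (adjusted p = 2.03e-21) and 24 of 24 coupling genes (1.3e-14) were higher. Lower were 53 of 53 mitosis (3.03e-17), 46 of 48 DNA replication (2.63e-19) and 79 of 84 ribosomal protein genes (1.19e-16). These 5 lists had adjusted p of 0.232, 0.232, 0.331, 0.232 and 0.317 with an estimated correlation.

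Between days 3 and 5, 30 of 41 sarcomere genes rose, while 16 of 25 cholesterol genes and 6 of 14 Notch genes fell. Myh4 rose 22.9-fold (SE 0.20, adjusted p = 3.49e-06), Mybpc1 10.9-fold (3.45, SE 0.18), Actn2 4.66-fold (2.22, SE 0.22) and Myh3 2.19-fold (1.13, SE 0.23, adjusted p = 0.0172). Of 41 sarcomere genes 30 were higher (35 adjusted over the list alone), at a median of 1.06 (adjusted p = 1.06e-19, adjusted p = 0.203 with an estimated correlation). Coupling (15 of 24, adjusted p = 2.6e-11) and energy metabolism genes (11 of 18, 6.27e-06) were higher, each with adjusted p = 0.203 with an estimated correlation. Of 25 cholesterol genes 16 were lower and 1 higher (20 and 1 adjusted over the list alone), as in Fdft1 (−0.69, SE 0.11) and Lss (−0.83, SE 0.16). The cholesterol median was −0.52 (adjusted p = 3.24e-09, adjusted p = 0.367 with an estimated correlation). Of 14 Notch genes 6 were lower (7 adjusted over the list alone), as in Hey1 (−1.48, SE 0.15) and Notch3 (−0.82, SE 0.12), with adjusted p = 0.00139 and adjusted p = 0.203 with an estimated correlation. Of 30 stress response genes 13 were higher (16 adjusted over the list alone), as in Ddit3 (0.97, SE 0.11), Herpud1 (0.96, SE 0.12) and Trib3 (1.60, SE 0.25). This list had a median of 0.36 (adjusted p = 1.3e-08, adjusted p = 0.367 with an estimated correlation).

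Mitosis genes were lower as a list at day 5 than at day 3 (3 of 53, 14 adjusted over the list alone; median −0.55, adjusted p = 2.6e-11, adjusted p = 0.434 with an estimated correlation). By genotype their median against day 0 went from −1.22 to −2.50 in the Fkbp5 knockdown and from −1.74 to −2.36 in the control, but from −2.09 to −1.95 in the Fkbp4 knockdown. Matrix genes were higher as a list (7 of 42, 15 adjusted over the list alone, as in Postn at 1.79, SE 0.17; adjusted p = 0.000678, adjusted p = 0.367 with an estimated correlation). Cdkn1c (−2.69, SE 0.34), Tmprss11f (−2.06, SE 0.49), Hhip (−1.72, SE 0.38), Sox8 (−1.69, SE 0.32) and the urea transporter Slc14a1 (−1.69, SE 0.42) were the largest decreases. The largest increases were the mitochondrial genes mt-Atp8 (7.51, SE 1.12), mt-Co2 (6.87, SE 1.45), mt-Nd4l (6.50, SE 1.17) and mt-Ts1 (5.28, SE 0.76), high in 1 or 2 of the 3 day 5 libraries. Fkbp5 rose 1.90-fold (0.92, SE 0.22, adjusted p = 0.0371), a call lost in 11 of 23 settings, and Cdk4 did not pass (−0.40, SE 0.12, adjusted p = 0.0765).

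Between days 0 and 3, 6709 genes changed (3391 higher, 3318 lower), between days 0 and 5, 7436 (3762 higher, 3674 lower), and between days 3 and 5, 791 (484 higher, 307 lower). Scaled by library size alone, 3526 were higher and 3830 lower between days 0 and 5, and 394 and 373 between days 3 and 5. For days 3 and 5 limma voom gave 295 higher and 279 lower. Leaving out any library, or any genotype, kept the first count between 5108 and 6628 and the second between 5703 and 7704. The third was 322 and 339 without the Fkbp4 knockdown library of day 3 or 5, 471 without the Fkbp5 knockdown day 5 library, and 250 and 232 without the control library of day 3 or 5. It was 333 and 179 without the Fkbp4 knockdown or the control genotype.

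The test for a knockdown effect that differs between day 0 and the late days called no muscle gene. It compares the size of the effect and cannot show when a target acts, since the knockdown was present at all 3 days. In simulated data it called 11% (Fkbp5) and 9% (Fkbp4) of genes changed 2-fold. For Fkbp5, 5 of 13372 genes passed (edgeR; 604 at an unadjusted p under 0.05; DESeq2 6, limma voom 0). The 1 protein-coding gene among them with a name was the cyclophilin Ppia (−4.58, SE 0.46, adjusted p = 0.0217; limma voom 0.0504). It stood at 1442, 122 and 98.8 CPM at days 0, 3 and 5 in the Fkbp5 knockdown against 110, 241 and 167 CPM in the control. In the Fkbp4 knockdown it was at 16.4 CPM at day 0, so the day 0 libraries differed widely. Of the words of Ppia, 19.27% occur in other genes. Xirp2, with 0 CPM in the Fkbp5 knockdown at day 0 and 20.4 and 12.1 CPM later, was next and did not pass (adjusted p = 0.197). Neither did Akap12 (1.70, SE 0.27), Pdlim3 (1.37, SE 0.22), Kansl2 (1.31, SE 0.21), Vdr (2.16, SE 0.37), Scp2 (−1.34, SE 0.20), Sarnp (−1.26, SE 0.21), Cdk2ap1 (−0.92, SE 0.20) and Srl (−1.42, SE 0.32). Myog (−0.31), Myh3 (−0.29) and Cdk4 (−0.16) did not pass, at adjusted p up to 0.974. For Fkbp4, 5 genes passed in edgeR, all of them unnamed models, with 396 at an unadjusted p under 0.05. Of the 13 genes DESeq2 called, 2 higher and 11 lower, 0 were among these 5, and limma voom called 1. Sprr1a (2.18, SE 0.32, adjusted p = 0.138), Zfp960 (3.99, SE 0.66), Hspa1b (1.64, SE 0.30), mt-Ts1 (6.65, SE 1.24) and Gabarapl2 (1.06, SE 0.23) came next and did not pass. The contractile genes Acta1 (−1.35, SE 0.25), Myh3 (−1.41, SE 0.26) and Mylpf (−1.46, SE 0.28) did not pass, nor did Casq2 (−1.63, SE 0.32) and Scp2 (−1.09, SE 0.20). The Fkbp5 count was 25 and 25 without the Fkbp4 knockdown day 3 or day 5 library, 21 and 14 without those of the Fkbp5 knockdown and 18 and 13 without those of the control. The Fkbp4 count was 24 and 27 without the Fkbp4 knockdown day 3 or day 5 library, 29 and 30 without those of the Fkbp5 knockdown and 26 without the control day 3 library.

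At single days, without a replicate and without a test, Myog in the Fkbp5 knockdown was below the control at day 3 (670 against 1511 reads, log2 ratio −1.23, 95% interval −1.37 to −1.10). The gap was smaller at day 5 (1083 against 1151 reads, −0.23, −0.35 to −0.11). At these days Myh3 was at −0.63 (−0.69 to −0.57) and −0.86 (−0.90 to −0.82), and Cdkn1a at −0.39 (−0.45 to −0.33) and −0.51 (−0.57 to −0.45). Ccnd1 lay above the control, at 0.69 (0.48 to 0.92) and 0.53 (0.27 to 0.80). Cdk4 was at −0.26 (−0.36 to −0.15) at day 3 and 0.27 (0.15 to 0.39) at day 5. In the Fkbp4 knockdown at day 0, Myog had 157 against 67 reads (1.07, 0.67 to 1.52) and Myh3 228 against 62 (1.71, 1.33 to 2.17). The sarcomere list in the Fkbp5 knockdown had medians of −0.01, −0.71 and −0.71 at days 0, 3 and 5, at percentiles 28.1, 0 and 0 of random lists. In the Fkbp4 knockdown they were 0.80, 0.09 and 0.17, at percentiles 100, 93.7 and 99.95. Coupling and endplate genes stood at −0.31, −0.34 and −0.51 in the Fkbp5 knockdown, at percentile 0 on each day. They stood at 0.43, 0.19 and 0.17 in the Fkbp4 knockdown. Mitosis genes stood at −0.06, 0.49 and −0.18 in the Fkbp5 knockdown and at 0.12, −0.15 and 0.53 in the Fkbp4 knockdown. At least 2-fold apart from the control were 161, 194 and 254 genes in the Fkbp5 knockdown and 118, 160 and 165 in the Fkbp4 knockdown at days 0, 3 and 5. Between the knockdowns 259, 351 and 461 genes differed that much.

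**Figure D3:**
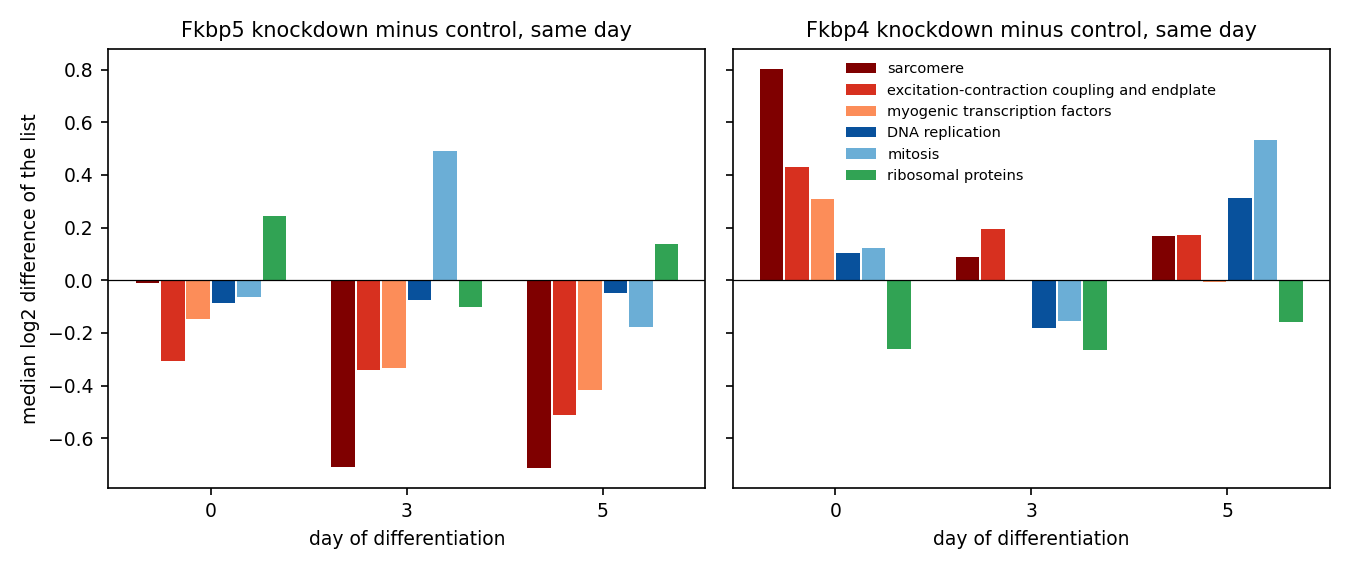
Median log2 difference from the control library of the same day for 6 gene lists in the Fkbp5 knockdown (left) and the Fkbp4 knockdown (right), 1 library against 1 library per bar. The sarcomere median is −0.71 at days 3 and 5 in the Fkbp5 knockdown and 0.80 at day 0 in the Fkbp4 knockdown.

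In a scan chosen after the counts were seen, genes lower in each knockdown shared a short word in their 3 prime UTR. The word GTTCGTT, found in 297 of 11387 UTRs, led the scan of 15891 words at each day in the Fkbp5 knockdown. Its z was −12.15, −12.39 and −11.12 at days 0, 3 and 5, against lowest permuted values of −5.13, −5.24 and −4.90. It was held by 53 of the 174 genes called lower with a UTR (30.5%) against 2.19% of genes not called, a share measured in the libraries the word was picked from. Among its holders, picked after their values were seen, were Rpn2, Alg10b, the transcription cofactor Wbp2 (−1.62, SE 0.09), the kinase p38 alpha Mapk14 (−1.12, SE 0.11), Pdlim5 (−1.01, SE 0.10) and Cdk6. In the Fkbp4 knockdown the word was GCTATGC, in 778 UTRs (z −9.30, −11.55 and −11.64). It was held by 33 of 98 genes called lower (33.7%) against 6.59%, among them Sod3, Ndufa1, Bag3, Tfdp2 and the metalloprotease Adam10 (−0.80, SE 0.10). In the other knockdown neither word passed its lowest permuted value, at z of −0.78, −0.32 and −0.48 for the first and −1.76, −1.04 and 0.23 for the second. Of the 19 sarcomere, coupling and myogenic factor genes called lower in the Fkbp5 knockdown, 0 held GTTCGTT and 2, Chrng and Rbm24, held 6 bases of it in a row.

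**Figure D4:**
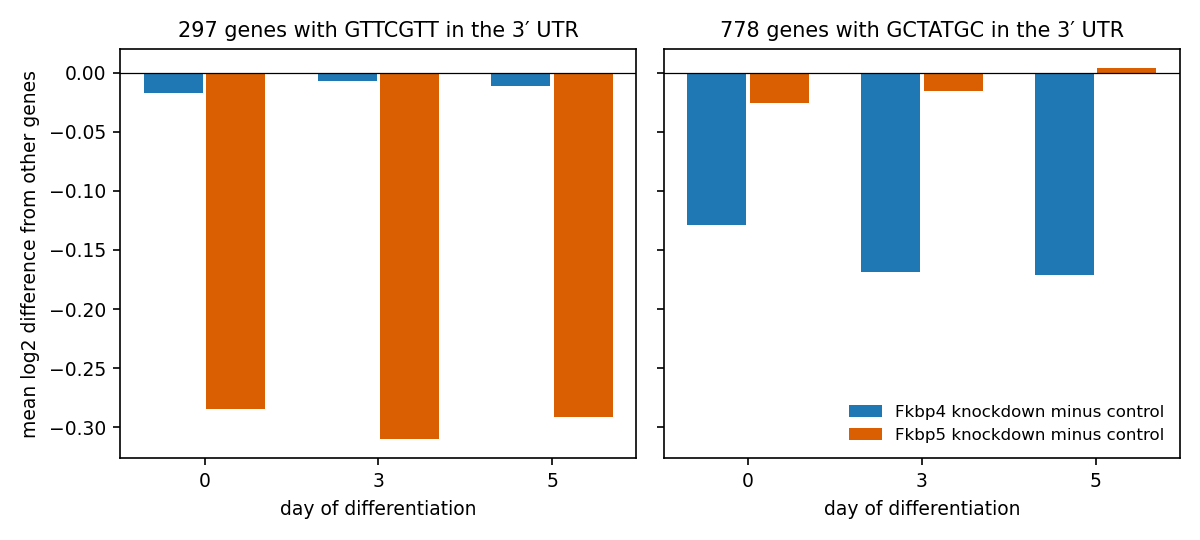
Mean log2 difference from other genes, by day, of the genes holding GTTCGTT (left) and GCTATGC (right) in their 3 prime UTR, for each knockdown minus the control library of the same day. Holders of GTTCGTT lie at −0.28, −0.31 and −0.29 in the Fkbp5 knockdown and holders of GCTATGC at −0.13, −0.17 and −0.17 in the Fkbp4 knockdown.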

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

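The tests on which genes share their sequence with other genes and on library depth were chosen after the result was seen, and the mitochondrial test was written before it. The flagged genes and lists were picked out because a knockdown effect differed between day 0 and the late days in a test of that difference, while the 25 transcripts and the mitochondrial genes set beside them were not. For the Fkbp5 knockdown, 5 genes differed: the pseudogenes Rpl31-ps14 (log2 −7.386), Rps27a-ps2 (7.126) and Gm13622 (9.585) and the cyclophilin Ppia (−4.579), at an adjusted p of 0.0217 each, and the pseudogene Gm10123 (8.828, adjusted p = 0.0267). Rpl31-ps14 stood at 131, 98.4 and 90.0 CPM at days 0, 3 and 5 in the Fkbp5 knockdown and at 0.66, 88.1 and 77.6 CPM in the control. For the Fkbp4 knockdown 5 pseudogenes differed: Gm5786 (−7.303, adjusted p = 0.000475), Gm13622 (11.116, 0.00732), Gm4342 (9.758, 0.0153), Gm16570 (3.658, 0.0153) and Gm10136 (−1.746, 0.0436). Gm5786 stood at 71.3, 0.18 and 0.42 CPM there and at 40.8, 23.9 and 36.0 CPM in the control.

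Of these genes Rpl31-ps14, Rps27a-ps2, Gm5786 and Gm4342 belong to 25 transcripts at 20 CPM or more in 1 library and at most 0.5 CPM in another of the same day, and Ppia, Gm13622, Gm10123, Gm16570 and Gm10136 do not. Gm10123, which shares 100% of its words with other genes, stood at 497 and 394.5 CPM in 2 day 0 libraries and at 1.05 CPM in the other. Of the 25, 23 are pseudogenes, and 17 (68%) share over 50% of their 31-base words with other genes, against a highest share of 32% in 1000 draws of matched genes. The draws were matched on expression and not on gene type, so pseudogenes that stayed level were not compared. Reads shared between near-identical copies could explain the 25 as a group, but the excess may only reflect that most are pseudogenes. Low depth was excluded because the libraries near 0 had 1.014 times the mean total of the others. Of mitochondrial genes only mt-Nd3 is among the 25, though mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l have 98.1% to 99.9% of their words in a copy on chromosome 1, and mt-Co3 reached 10440 CPM in the Fkbp5 knockdown day 5 library and at most 34.8 CPM elsewhere. Without that stretch the mitochondrially encoded list in the Fkbp5 knockdown stayed past the test at a median of 0.297 (5 members, adjusted p = 0.00675 at the preset correlation), just under the bound of 0.3 set beforehand for excluding the copy, so whether it is the whole cause stays open. Against that, mt-Nd2 (0.64) and mt-Cytb (0.59), picked after their values were seen, share 0% of their words with the copy and were called higher, and no biological explanation was tested.

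In the same test of lists, the effect of the Fkbp5 knockdown on sarcomere genes was lower at the late days than at day 0 by a median of −0.733 (adjusted p = 3.73e-08, adjusted p = 0.675 with an estimated correlation). Interferon response genes moved up (0.379, adjusted p = 0.000592, adjusted p = 0.675 with an estimated correlation), as did YAP and TGF-beta targets (0.377, adjusted p = 0.00562, adjusted p = 0.798 with an estimated correlation). The unfolded protein response (−0.31, adjusted p = 6.82e-05), ribosomal proteins (−0.2, 6.82e-05) and nuclear-encoded oxidative phosphorylation (−0.208, 1.91e-05) moved down, each with adjusted p = 0.798 with an estimated correlation. The call for YAP and TGF-beta targets was lost without the Fkbp5 knockdown day 5 (0.0948) or the control day 5 library (0.206), and those for oxidative phosphorylation (0.0502) and ribosomal proteins (0.0868) without the control day 3 library. For the Fkbp4 knockdown, sarcomere (−0.719, adjusted p = 2.71e-10), coupling and endplate (−0.216, 0.00285) and matrix genes (−0.226, 0.00245) moved down, each with adjusted p = 0.899 with an estimated correlation, and cholesterol synthesis up (0.332, 0.0117, adjusted p = 0.999 with an estimated correlation). The cholesterol call was lost without the Fkbp4 knockdown day 3 (0.394) or the control day 3 library (0.832), and the matrix call without the control day 5 library (0.0583). No member of these lists was called over all genes by edgeR. Adjusted over the list alone, 10 sarcomere and 2 coupling genes were lower in the Fkbp4 test. Both sarcomere shifts rest on the same control libraries. From day 0 to days 3 and 5 the sarcomere median rose by 4.875 and 6.472 in the control. It rose by 4.368 and 5.226 in the Fkbp5 knockdown and by 4.017 and 5.464 in the Fkbp4 knockdown. No day 0 library was left out in these list tests. A control day 0 library that stood apart can therefore not be told from 2 knockdown effects.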

How the results depend on the processing

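Genes called against day 0 held best. Of named or listed genes, 123 of 128 called from day 0 to 3 and 127 of 130 from day 0 to 5 passed in every setting that tested them. The counts were 2 of 39, 0 of 33 and 0 of 95 for Fkbp5 against control, Fkbp4 against control and Fkbp5 against Fkbp4, and 15 of 83 from day 3 to 5. A setting that left a gene out was not counted against it. Of the called lists, 7 of 9, 5 of 6 and 10 of 13 for these genotype comparisons, 12 of 13 and 11 of 12 for days 3 and 5 against day 0 and 11 of 17 from day 3 to 5 passed without each library in turn. Across all settings of named genes, 20204 values kept their direction and side of the threshold, 1385 were weaker, 446 stronger and 1 reversed; of lists, 2118, 161, 81 and 8. A change of sign was counted as reversed only if 1 of the settings passed the test. In that order of the 3 genotype comparisons, counts were 866, 690 and, from day 3 to 5, 1578 with no low-count filter; 3, 0 and 4 without the day term, and 127 from day 3 to 5 without the genotype term; 41, 20 and 718 without genes holding a word or its core; and 94, 41 and 327 at 2-fold or more, with 2606, 3052 and 270 for the days. For Fkbp5 and Fkbp4 against control they were 413 and 240 with protein-coding nuclear genes only and 446 and 312 without genes that share over 20% of their words. DESeq2 gave 224 for Fkbp4 against control and 1094 between the knockdowns, and the 6 compared libraries alone 337 and 961. The interactions of Fkbp5 and Fkbp4 with differentiation had 107 and 95 genes with no filter, 0 and 1 with limma voom, 1 and 0 with coding genes only, 1 and 0 without genes sharing words, and 13 for Fkbp4 with DESeq2. With an estimated correlation 0 lists passed in all 8 comparisons. With fry 0 passed for Fkbp5 against control, Fkbp4 against control and both interactions, 23 and 20 for days 3 and 5 against day 0 and 8 from day 3 to 5. Of the 13 lists called for Fkbp5 against Fkbp4, 10 passed with fry. With at least 200 reads the 2-fold differences at days 0, 3 and 5 numbered 58, 67 and 85 (Fkbp5), 46, 65 and 56 (Fkbp4) and 112, 149 and 201 (Fkbp5 against Fkbp4). With single libraries left out in turn, counts ranged from 40 to 296, 4 to 259 and 487 to 2106 for the genotype comparisons, 232 to 924 from day 3 to 5, and 5 to 25 and 7 to 30 for the interactions, whose lists numbered 5 to 10 and 5 to 7. The lowest counts without a whole day were 36, 4 and 250 for the genotype comparisons, and 179 from day 3 to 5 without the control genotype. Reversals, whose cause was not tested, came with single libraries left out: mitosis went from −0.245 to 0.316 (Fkbp5 against control), −0.331 to 0.171 (Fkbp5 against Fkbp4), −0.375 to 0.688 (Fkbp5 interaction) and −0.434 to 0.64 (Fkbp4 interaction), mitochondrially encoded genes from −0.386 to 0.869 and −0.455 to 0.826 in the 2 interactions, DNA replication from −0.196 to 0.235 (Fkbp4 interaction), and mt-Nd3 from −1.191 to 6.993 from day 3 to 5. A group left with 1 library was assumed to vary like the others. Depth limits Fkbp5 itself, with 14 to 21 reads per knockdown library.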

Other observations

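Beyond the muscle genes, the transcripts that fell with the Fkbp5 knockdown included 2 kinases tied to differentiation and the cell cycle, Mapk14 (p38 alpha, −1.12, SE 0.11, adjusted p = 0.00159) and Cdk6, and the signalling subunit Pik3cb (−1.02, SE 0.20, adjusted p = 0.0306). The actin regulators Marcksl1 (−1.40, SE 0.15) and Arpc1a (−1.12, SE 0.11) fell with them. With the Fkbp4 knockdown fell the mitochondrial trafficking protein Trak2 (−1.08), the SUMO-activating subunit Uba2 (−0.95), the elongation factor Tcea1 (−0.94, adjusted p = 0.00684) and the acid ceramidase Asah1 (−0.91, SE 0.11). All of these were picked after their values were seen, as genes that hold the word described next.

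The tests of the word at days 3 and 5 and of UTR length and GC content were chosen after the result was seen, and that of the target transcripts was written before it. In each knockdown a part of the genes called lower, 30.5% for Fkbp5 and 33.7% for Fkbp4, hold the same 7-base word in the 3 prime UTR, which off-target silencing through the seed of the knockdown RNA could produce. The word found at day 0 returned at both later days, at a z no higher than −11.12 for Fkbp5 and −11.55 for Fkbp4. Each target transcript holds its word, as do 5.21% and 11.89% of transcripts of similar length, at position 1098 of 3858 in Fkbp5 and first at 646 of 2678 in Fkbp4, outside the 3 prime UTR in both. A trend with UTR length or GC content, as fitted, was excluded. Both were regressed out in the scan that picked the words, where the weakest leading z was −9.3 against a lowest permuted value of −4.99. No scan without that step was run, so this adds no evidence apart from the scan itself. No biological explanation was tested, and the knockdown sequences were not used here.

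The tests of the muscle genes lower in the Fkbp5 knockdown were all written before their results. For the called muscle genes as a group, a direct hit through the word in the 3 prime UTR was excluded. Of them 10.5%, namely Chrng and Rbm24, hold 6 bases of it. The share was 56.9% of all genes called lower with a UTR and 15.6% of all tested genes with one. Without all holders the sarcomere list kept a median of −0.54 (31 members, adjusted p = 2.73e-10 at the preset correlation). A hit on Chrng or Rbm24, or outside the annotated 3 prime UTR, was not excluded. A single control or Fkbp5 knockdown library acting alone was excluded too, at the preset correlation. The sarcomere list had a highest adjusted p of 8.8e-07 without each library in turn. Of its 41 members 39 and 40 were lower at days 3 and 5, each day against its own control. A difference shared by all libraries of a genotype stays in each of these fits, so it cannot be excluded this way. On all libraries the list had adjusted p = 0.35 with an estimated correlation and 0.117 with fry. A delay of the whole differentiation programme stays open, as 1 of 4 combinations of a proliferation list with a late day lay above the upper range of random lists, mitosis at day 3 (percentile 100), while mitosis at day 5 (0.08) and DNA replication at days 3 and 5 (5.73 and 17.96) did not; loss of Fkbp5 itself and indirect effects of the word also stay open, untested.

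Of the 10 ways to divide the 6 libraries of each comparison, only the true one gave as many calls (1 of 10), and the highest other count was 3, 2, 2, 0, 0 and 3 for Fkbp5 against control, Fkbp4 against control, Fkbp5 against Fkbp4, days 0 to 3, days 0 to 5 and days 3 to 5. That test was chosen after the result was seen, and 10 divisions are too few for a share under 0.05. The 2 knockdown effects had a covariance of 0.0245 across 10900 genes. It was 0.0188 to 0.0278 in simulations where neither knockdown changed any gene and both were set against the same control libraries. Their correlation was lower than simulated (0.205 against 0.418 to 0.560), as was the share of genes with the same sign (52.3% against 66.2% to 67.7%). In opposite directions 6 genes were called against 0, and 3 were called lower in both against 0 to 2. Were the observed calls independent, 1.69 genes would be lower in both. Effects unrelated to each other would also lower the correlation and add calls. Simulations without any effect therefore cannot tell opposed, shared and unrelated effects apart.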
